A study of Homo sapiens with 5 samples.

How the data were processed

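Total RNA from Kelly cells, an established human neuroblastoma line with MYCN amplification, was hybridised to Affymetrix arrays 48 h after siRNA transfection. The 5 arrays fall into 3 groups by their labels: 1 array of cells given a control siRNA, 2 arrays of cells given siRNAs against lncMycN and 2 arrays of cells given siRNAs against N-Myc, the protein encoded by MYCN. The 2 arrays of a target carry different siRNAs, No. 1 and No. 2, and serve as its replicates. Nothing in the labels says that they came from separate cultures. The p-values of single genes thus measure only the spread between these arrays, which combines array noise with any difference between the reagents. The number of arrays limits the precision of every value.

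The deposited values are signal intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name MAS5; a version, a scaling target and any later step are not given in the sources used here. The values have features that MAS5 alone does not give: 54.2% of the 54675 probe sets hold the exact same value on 2 or more arrays, and at any rank the arrays differ by at most 0.14 on the log2 scale. These features are those of values matched in distribution across the 5 arrays, so the step that produced them stays unknown. Array medians lay between 48.7 and 49.8, and the highest signal was 34923. Every column of the table was assigned to a labelled sample.

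Probe sets were named from the platform annotation, with symbols updated by gene ID through the RefSeq gene table. Of all probe sets, 41097 had 1 gene symbol, 1801 had several and were left unnamed, and 11777 were not in the annotation table and are unnamed here; 41043 of those with 1 symbol matched the RefSeq table. No genome build is given in the sources used here, so no coordinates are printed. The 62 control probe sets were left out. The values were used as log2 without an offset and without further normalization. Probe sets with a mean log2 signal under the median of all probe sets, a signal of 49.2, were removed, and each gene was represented by its brightest remaining probe set, which left 12890 genes.

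Differences were tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 5 arrays, with 2 residual degrees of freedom, and the variances were moderated with an intensity trend, which added 1.63 prior degrees of freedom. The lone control array was assumed to vary like the other groups. The median residual SD after moderation was 0.17 on the log2 scale, and 99 genes had a residual variance of 0 before it. The 3 comparisons were N-Myc siRNA against control, lncMycN siRNA against control, and lncMycN siRNA against N-Myc siRNA; the last does not use the control array. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Genes at least 2-fold from the control with both siRNAs of a target were counted without a test. Beside them stands the count in 100 simulations of unchanged arrays that share the control and have the moderated residual spread. The simulated control has that spread too. It is wider than the observed covariance between targets allows, unless opposite effects of the targets lower that covariance. Correlations of fold changes were computed across genes, which are not independent replicates.

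The 16 gene lists were fixed before the data were examined: MYC and MYCN induced genes of ribosome biogenesis and the nucleolus, MYC and MYCN induced genes of nucleotide, polyamine and one-carbon metabolism, ribosomal proteins, G1/S and DNA replication, G2/M and mitosis, p53 targets, neuronal differentiation, adrenergic regulators and catecholamine synthesis, markers of mesenchymal, fibroblast and Schwann cells, interferon and double-stranded RNA response, unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, apoptosis regulators, DBHS and paraspeckle proteins, and the 2p24 neighbours of MYCN. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 16 lists of a comparison. At the preset correlation its p-values set the members of a list against the other genes. They rest on the spread over genes, not on that between replicate arrays. The same test with an estimated correlation and limma's fry were also run. With an estimated correlation, camera takes its p-values from the 2 residual degrees of freedom, which few lists can pass. A call lost there therefore does not show that correlation between members had produced it.

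The genes named in the text follow a rule set in advance. It takes MYCN with its 2p24 neighbours, and for each comparison the 12 highest and 12 lowest genes past the threshold with the same sign in every replicate, filled up with the genes of largest moderated t where fewer pass. It also takes up to 4 members of each list with the largest moderated t. Locus, open reading frame, KIAA and FAM names were skipped, as were names ending in -AS with or without a number. Antisense genes under other names, such as RFPL1S, were kept. Genes named outside this rule are said to be so.

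The fit was tested on simulated data of the comparison of N-Myc siRNA against control, with 12890 genes. At the observed spread it recovered 11% of 100 genes changed 2-fold and 66% of 100 genes changed 4-fold, with 2 false calls. A list of 25 members shifted by -0.3 on the log2 scale was called in 20 of 20 simulations, and 0 of 300 tests of other lists were called. These simulated genes vary independently, which real list members do not.

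The alternatives were quantile normalization, centring on array medians, log2 of the value plus 32, no filter, a filter at the upper quartile, the mean of a gene's probe sets, all probe sets, no intensity trend, only the groups compared, other fold thresholds, each other MYCN probe set, the siRNA number as a block and each siRNA array left out in turn.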

Results

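Gene expression was measured on 5 Affymetrix arrays of Kelly cells, a human neuroblastoma line in which the oncogene MYCN is amplified. The cells had been transfected for 48 h with a control siRNA (1 array), with siRNAs against lncMycN (2 arrays, a different siRNA on each) or with siRNAs against N-Myc (2 arrays, likewise). The labels describe the lncMycN arrays as a knockdown of that RNA but give no sequence or gene identifier for it. Median signals per array lay between 48.7 and 49.8, and 12890 genes passed the signal filter. Values below are log2 differences from the control array unless stated otherwise, with n = 2 siRNAs per target and n = 1 control array.

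MYCN itself was measured first, because it is the target of the N-Myc siRNAs. On its brightest probe set, 209757_s_at, MYCN lay at the 99.7th percentile of signal, with 20720 on the control array. The signal was 17921 and 19497 with the N-Myc siRNAs, a difference of -0.15 (SE 0.08, 95% interval -0.37 to 0.07). It was 18692 and 18372 with the lncMycN siRNAs, a difference of -0.16 (SE 0.08, 95% interval -0.38 to 0.06). Neither passed the limma test (adjusted p = 0.906 and 1). The targets differed by -0.01 (95% interval -0.19 to 0.17) on this probe set. Other MYCN probe sets past the filter gave other sizes. On 211377_x_at the difference was -0.51 with N-Myc siRNAs and -0.29 with lncMycN siRNAs (SE 0.08 for each). On 209756_s_at it was -0.73 and -0.57 (SE 0.73 for each), with the N-Myc arrays far apart at -0.03 and -1.44. On 234376_at it was 0.21 and -0.12 (SE 0.14 for each). Between targets, lncMycN minus N-Myc, the difference was 0.22 (SE 0.06) on 211377_x_at and 0.17 (SE 0.59) on 209756_s_at. It was -0.32 (SE 0.12) on 234376_at, so the probe sets did not agree on its sign. The antisense gene MYCNOS, which overlaps MYCN, had differences of 0.56 with N-Myc siRNAs and -0.34 with lncMycN siRNAs on its brightest probe set. On its other probe set, 216188_at, the lncMycN arrays lay at -1.56 and -0.58 and the N-Myc arrays at -0.24 and 0.18. The neighbour DDX1, an RNA helicase gene often co-amplified with MYCN, had differences of -0.25 with N-Myc siRNAs and -0.04 with lncMycN siRNAs. NBAS had differences of 0.07 and -0.15. Of the 2p24 neighbours, LRATD1, KIDINS220 and TRIB2 had the largest moderated t between the targets. With N-Myc and lncMycN siRNAs, LRATD1 was at -0.48 and 0.63, KIDINS220 at 0.51 and 0.06, and TRIB2 at -0.10 and -0.71. None of these passed the limma test. For LRATD1 and KIDINS220 another probe set had the opposite sign in some comparisons. The small values of NBAS with N-Myc siRNAs and of DDX1 with lncMycN siRNAs took the other sign when an array was left out.

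**Figure D1:**
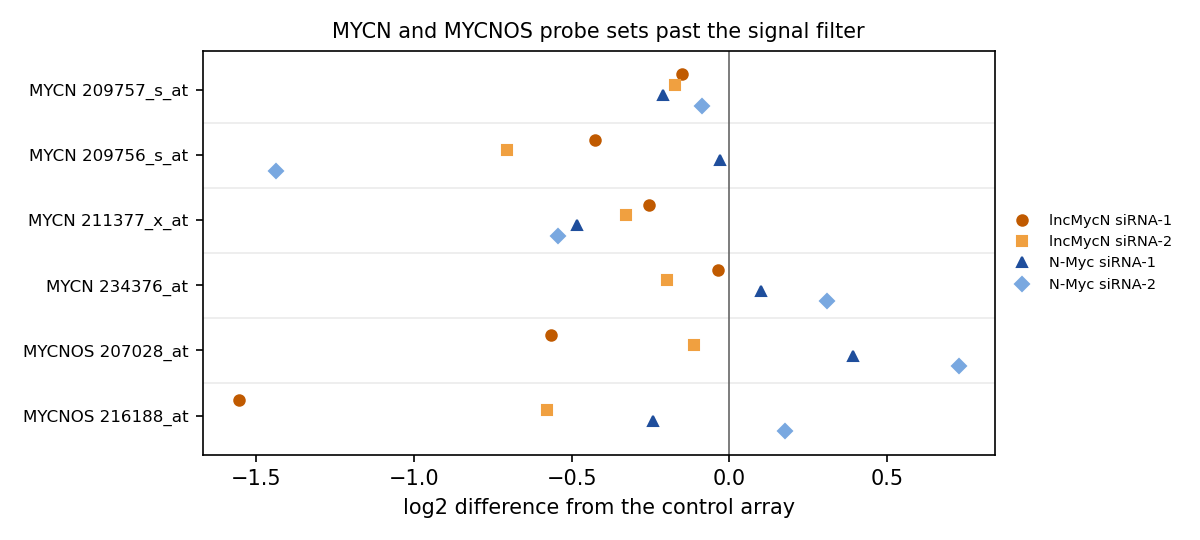
Log2 difference from the control array (horizontal axis) for each probe set of MYCN and MYCNOS past the signal filter (vertical axis), with 1 point per siRNA array. On the brightest MYCN probe set, 209757_s_at, all 4 arrays lie between -0.21 and -0.09, while the 209756_s_at points reach -1.44.

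With the N-Myc siRNAs, genes of ribosome biogenesis and the nucleolus, known as MYC and MYCN induced, fell as a list at the preset correlation of camera (adjusted p = 3.99e-08). This call was lost with an estimated correlation (adjusted p = 0.467). Their median difference was -0.43, and 24 of 25 measured members were lower on both arrays. Examples were MYBBP1A, a nucleolar Myb-binding protein, at -0.87 (SE 0.18), the U3 processome component UTP20 at -0.98 (SE 0.37), NOP16 at -0.60 (SE 0.21) and WDR12 at -0.43 (SE 0.16). Another probe set of NOP16 had the opposite sign. The list of nucleotide, polyamine and one-carbon metabolism also fell, with a median of -0.29 and 25 of 29 members lower, 22 on both arrays (adjusted p = 0.000114, but adjusted p = 0.467 with an estimated correlation). Among its members, the purine synthesis enzyme PAICS was at -0.52 (SE 0.13), PRPS2 at -0.94 (SE 0.31), DHODH of pyrimidine synthesis at -0.50 (SE 0.19) and NME1 at -0.21 (SE 0.06). The G1/S and DNA replication list fell by a median of 0.21, with 27 of 30 members lower, 24 on both arrays, and its adjusted p = 0.000687 became adjusted p = 0.467 with an estimated correlation. MCM2 was at -0.38, MCM7 at -0.45, POLA1 at -0.46 and E2F1 at -0.57. Genes of neuronal differentiation rose as a list, by a median of 0.15, with 19 of 28 members higher, 16 on both arrays (adjusted p = 0.0117). This call was lost with an estimated correlation (adjusted p = 0.467), without the filter, and without either lncMycN array or N-Myc siRNA-2. Its leading members were STMN2 at 0.87 (SE 0.18), the microtubule protein gene DCX at 1.31 (SE 0.45), RBFOX3 at 0.42 (SE 0.09) and the neuropeptide gene NPY at 0.59 (SE 0.22). These members also lay above the control on both lncMycN arrays, so they do not mark the N-Myc siRNAs alone. There STMN2 lay at 0.58 and 0.35, DCX at 0.36 and 1.22, RBFOX3 at 0.32 and 0.29, and NPY at 0.61 and 0.32.

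Without N-Myc siRNA-2 the median of nucleotide metabolism was -0.19. No member of these lists passed the limma test over all genes, and 0 passed when adjusted over the list alone. The other 12 lists were not called. Their medians and adjusted p were 0.01 and 0.324 for ribosomal proteins, -0.02 and 0.330 for G2/M, 0.15 and 0.192 for p53 targets, and 0.08 and 0.762 for the adrenergic list. They were 0.10 and 0.0635 for mesenchymal and Schwann cell markers, 0.09 and 0.472 for interferon response, -0.12 and 0.0678 for unfolded protein response, and -0.09 and 0.330 for cholesterol synthesis. They were -0.14 and 0.0678 for glycolysis and hypoxia, 0.05 and 0.762 for apoptosis regulators, -0.09 and 0.294 for paraspeckle proteins, and -0.12 and 0.472 for the 2p24 neighbours.

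For single genes, limma called 0 of 12890 with the N-Myc siRNAs at the adjusted threshold. At an unadjusted p under 0.05 there were 717 genes, 411 higher and 306 lower. SEs against the control give its lone array the spread between siRNAs. Unless the targets have opposite effects, that is wider than the covariance between targets allows, so this count is not placed against chance. The genes of largest moderated t therefore did not pass, and they differed from the control by 1.41-fold to 3.26-fold. The higher ones were SMIM14 at 1.44 (SE 0.19), SUSD2 at 1.02 (SE 0.08), the cytidine deaminase gene APOBEC3B at 0.92 (SE 0.10), TMEM187 at 0.89, UEVLD at 0.76, ZFP92 at 0.67, LYRM9 at 0.64, RPAP3-DT at 0.63, the small heat shock protein gene HSPB2 at 0.62, ITPRIPL1 at 0.59, HAPLN4 at 0.58 and TDRG1 at 0.50. The lower ones were TAF4B, which encodes a TFIID subunit, at -1.71 (SE 0.25), the organic anion transporter gene SLCO4A1 at -1.47 (SE 0.17), TMEM117 at -1.27, the mitochondrial carrier gene SLC25A30 at -1.22, the neurexophilin gene NXPH2 at -1.18, PROSER2 at -1.02, N4BP2L1 at -0.91, GCNT1 at -0.89, L3MBTL3 at -0.84, HOMER2 at -0.68, PRSS23 at -0.65 and CCDC150 at -0.61. Several of them were dim, such as HAPLN4 at a mean signal of 50.3, close to the filter, and another probe set of N4BP2L1 had the opposite sign. Several also lay about as far from the lone control array with the lncMycN siRNAs, so they do not mark the N-Myc siRNAs alone. There UEVLD lay at 1.07 and 0.96, ITPRIPL1 at 0.62 and 0.67, ZFP92 at 0.59 and 0.59, and HAPLN4 at 0.48 and 0.53. HSPB2, TDRG1, RPAP3-DT, NXPH2 and CCDC150 were alike in this. Others were not, such as APOBEC3B at -0.67 and -0.82.

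At least 2-fold differences with both N-Myc siRNAs were seen for 62 genes, 22 higher and 40 lower. Unchanged arrays sharing 1 control gave 86.0 such genes on average in simulation, but that simulation gives every array the moderated residual spread. Its covariance between targets, 0.0637, exceeds the observed 0.0298, which opposite effects of the targets could also lower. The baseline may thus be too wide for these arrays, and the count is not placed against chance. Named after their values were seen, the lower genes included the GABA receptor subunit gene GABRA5 (-1.95 and -2.73), LPAR3 (-1.38 and -2.56), SOX2 (-1.38 and -2.20), the nucleolar protein gene LYAR (-1.78 and -1.07), SNAI2 (-1.08 and -1.69) and the Wnt pathway factor LEF1 (-1.12 and -1.30). The higher ones included the galectin gene LGALS1 (1.13 and 2.65), the cyclin-dependent kinase inhibitor gene CDKN1C (1.52 and 1.94), the Wnt receptor gene FZD7 (1.49 and 1.31) and the p53 target TP53I3 (1.30 and 1.43). Some of these values are uncertain, with an SE of 0.86 for SOX2 and 0.78 for SNAI2. SNAI2 also had a mean signal of 53.8, near the filter. With the lncMycN siRNAs LEF1 lay at -1.86 and -0.60, TP53I3 at 0.95 and 0.42, and SNAI2 at 0.20 and -1.40.

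With the lncMycN siRNAs, both cell cycle lists fell at the preset correlation (adjusted p = 5.48e-07 for G1/S and 5.99e-06 for G2/M). Both calls were lost with an estimated correlation (adjusted p = 0.631 and 0.483). The G1/S and DNA replication list had a median of -0.33, with 28 of 30 members lower and 22 lower on both arrays. The DNA ligase gene LIG1 was at -0.63 (SE 0.17), the replicative helicase subunit MCM6 at -0.53 (SE 0.16), GINS2 at -0.42 (SE 0.16) and the chromatin assembly factor CHAF1A at -0.56 (SE 0.23). Another probe set of GINS2 had the opposite sign. The G2/M and mitosis list had a median of -0.23, with 29 of 30 members lower and 26 lower on both arrays. The kinetochore motor gene CENPE was at -0.73 (SE 0.21), the centromeric histone gene CENPA at -0.45 (SE 0.18), TPX2 at -0.38 and the mitotic kinase gene PLK1 at -0.23. The p53 target list rose, with a median of 0.24 and 17 of 22 members higher, 10 on both arrays (adjusted p = 0.0343). This call was lost with an estimated correlation (adjusted p = 0.907), without the filter, and without lncMycN siRNA-1 or either N-Myc array. Among its members were the death receptor gene TNFRSF10B at 0.59 (SE 0.21), TP53I3 at 0.69 (SE 0.29), RRM2B at 0.41 (SE 0.19) and CCNG1 at 0.36 (SE 0.22). These members also lay above the control on both N-Myc arrays, so they do not mark the lncMycN siRNAs alone. There TNFRSF10B lay at 0.50 and 0.19, TP53I3 at 1.30 and 1.43, RRM2B at 0.39 and 0.20, and CCNG1 at 0.26 and 0.15. The p53 list's median was 0.41 on the first lncMycN array and 0.05 on the second.

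No member passed the limma test over all genes, and 0 passed when adjusted over the list alone. The MYC and MYCN induced lists were not called, with a median of -0.03 and adjusted p = 0.50 for ribosome biogenesis and -0.07 and 0.352 for nucleotide metabolism. Cholesterol synthesis had a median of -0.23 and an adjusted p of 0.0534. The medians and adjusted p of the others were 0.03 and 0.112 for ribosomal proteins, -0.09 and 0.353 for neuronal differentiation, -0.09 and 0.492 for the adrenergic list, -0.03 and 0.629 for interferon response, and 0.03 and 0.888 for unfolded protein response. They were -0.04 and 0.421 for glycolysis and hypoxia, -0.10 and 0.134 for paraspeckle proteins, and -0.25 and 0.112 for the 2p24 neighbours. Mesenchymal and Schwann cell markers (adjusted p = 0.888) and apoptosis regulators (adjusted p = 0.915) had medians within 0.01 of no difference.

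For single genes, limma called 0 of 12890 with the lncMycN siRNAs, and 521 had an unadjusted p under 0.05, with 313 higher and 208 lower, a count not placed against chance for the same reason. The genes of largest moderated t, none past the threshold, differed by 1.36-fold to 3.09-fold. The higher ones were TOX, an HMG-box factor, at 1.49 (SE 0.19), the ubiquitin ligase gene RNF149 at 1.11 (SE 0.16), the sphingosine-1-phosphate phosphatase gene SGPP2 at 1.08 (SE 0.10), UEVLD at 1.01, the neuropeptide gene NPFF at 0.83, ITPRIPL1 at 0.64, MID2 at 0.56, PCDHAC1 at 0.53, HSPB2 at 0.49, TDRG1 at 0.48, INPP5D at 0.45 and AKR1C6P at 0.44. The lower ones were PCOLCE, an enhancer of procollagen processing, at -1.63 (SE 0.24), the membrane-cytoskeleton linker radixin, RDX, at -1.29 (SE 0.19), RNASEH1-DT at -1.27, the nucleoporin gene NUP50 at -1.10 (SE 0.15), ARHGAP11A at -0.96, ZGRF1 at -0.96, ZNF800 at -0.92, NXPH2 at -0.89, RFPL1S at -0.82, APOBEC3B at -0.74, CCDC150 at -0.59 and PRXL2C at -0.49. RDX and NUP50 were well above the filter, with mean signals of 2572 and 2788, while another probe set of ZNF800 had the opposite sign. Several of these genes lay about as far from the lone control array with the N-Myc siRNAs, so they do not mark the lncMycN siRNAs alone. There ITPRIPL1 lay at 0.56 and 0.62, MID2 at 0.49 and 0.49, INPP5D at 0.50 and 0.45, and ZNF800 at -0.88 and -0.91. HSPB2, TDRG1, NXPH2 and CCDC150 were alike in this. Others were not, such as TOX at 0.03 and -0.18 and RDX at 0.04 and -0.12. At least 2-fold differences with both lncMycN siRNAs were seen for 30 genes, 10 higher and 20 lower. The same simulation gave 86.0, a baseline that may be too wide here as well. Named after their values were seen, they included the corticotropin-releasing hormone gene CRH (-1.77 and -3.34), the chemokine receptor gene ACKR3 (-1.22 and -3.27), PLXNA2 (-1.49 and -1.39), CD9 (-1.17 and -1.70), FSD1L (1.41 and 1.83) and PARD6B (1.53 and 1.20). CRH and ACKR3 had SEs of 1.10 and 1.63, and FSD1L lay at 0.65 and 1.34 with the N-Myc siRNAs.

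**Figure D2:**
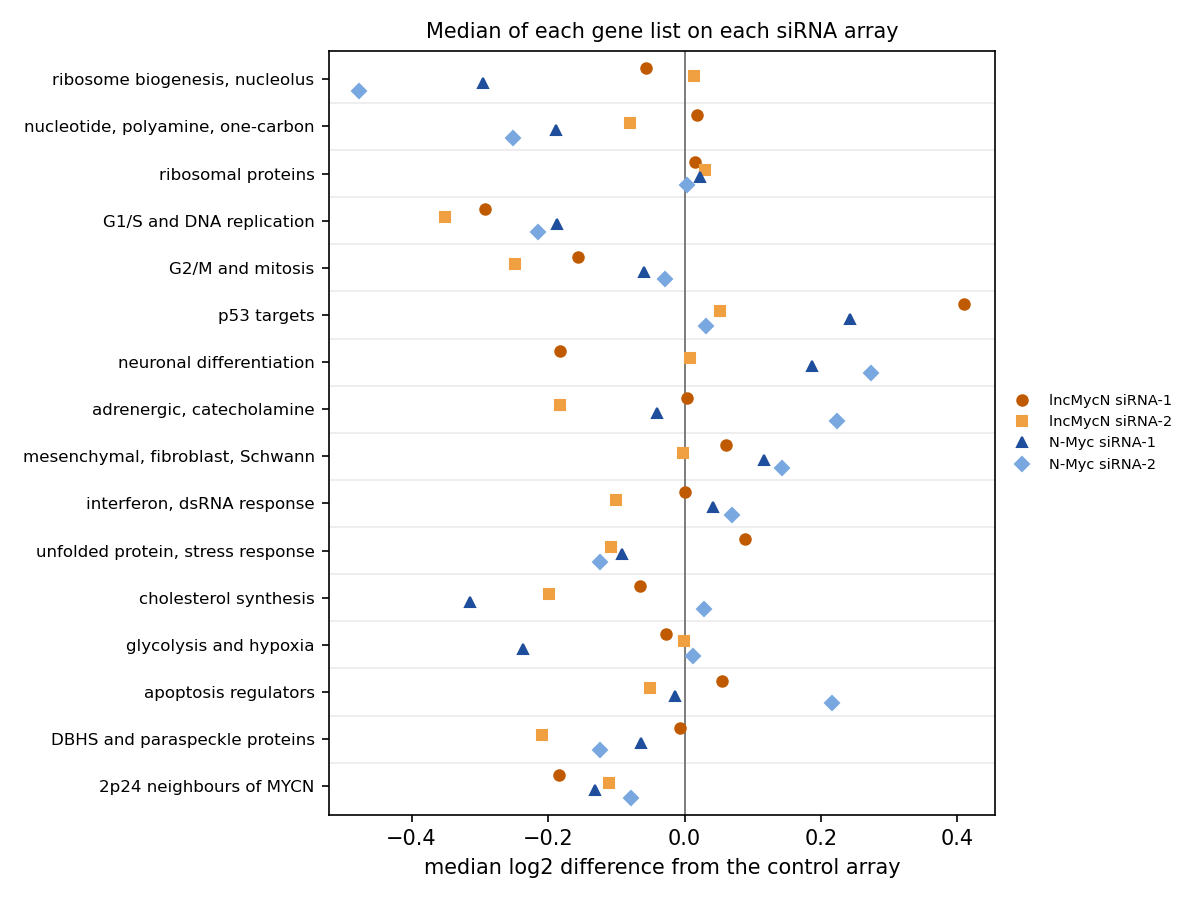
Median log2 difference from the control array over the measured members of each gene list (horizontal axis; 1 list per row), with 1 point per siRNA array. Ribosome biogenesis lies at -0.30 and -0.48 on the N-Myc arrays and at -0.06 and 0.01 on the lncMycN arrays, while G1/S lies between -0.35 and -0.19 on all 4.

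The direct comparison of the targets does not depend on the control array. Genes of ribosome biogenesis were higher with lncMycN siRNAs than with N-Myc siRNAs by a median of 0.43, with 22 of 25 members higher (adjusted p = 1.49e-06, but adjusted p = 0.576 with an estimated correlation), among them MYBBP1A at 0.66 (SE 0.15), NOB1 at 0.87 (SE 0.23), WDR12 at 0.55 (SE 0.13) and NOP2 at 0.57 (SE 0.16). Nucleotide metabolism was higher by a median of 0.18, with 20 of 29 members higher (adjusted p = 0.00401, but adjusted p = 0.576 with an estimated correlation), including PRPS2 at 1.01 (SE 0.25), PAICS at 0.45, DHODH at 0.49 and SHMT2 at 0.42. Neuronal differentiation was lower by a median difference of -0.32, with 22 of 28 members lower (adjusted p = 0.000548, but adjusted p = 0.508 with an estimated correlation). The receptor tyrosine kinase gene RET was at -1.98 (SE 0.30), the adhesion genes NCAM1 and L1CAM at -1.09 (SE 0.15) and -1.44 (SE 0.34), and the neuropeptide gene VIP at -1.41 (SE 0.27). Against the control, RET lay at -0.65 and -1.37 with the lncMycN siRNAs and at 0.90 and 1.04 with the N-Myc siRNAs. The G2/M list was lower by a median difference of -0.14, with 25 of 30 members lower (adjusted p = 0.00401, but adjusted p = 0.508 with an estimated correlation), including CENPA at -0.67 (SE 0.15), CDC25C at -0.52, BIRC5 at -0.46 and CCNB1 at -0.26. Another probe set of CDC25C had the opposite sign. The unfolded protein and integrated stress response list was higher by a median of 0.19, with 19 of 24 members higher (adjusted p = 0.0347, but adjusted p = 0.735 with an estimated correlation), including CEBPB at 0.69, SLC3A2 at 0.62, ATF4 at 0.39 and STC2 at 0.37.

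Members with the same sign between each lncMycN and each N-Myc array were fewer: 18 of 25 higher for ribosome biogenesis, 16 of 29 higher for nucleotide metabolism, 12 of 28 lower for neuronal differentiation, 11 of 30 lower for G2/M and 9 of 24 higher for unfolded protein response. No member of these 5 lists passed over all genes or when adjusted over the list alone. Leaving out N-Myc siRNA-2 ended the calls of nucleotide metabolism, G2/M and unfolded protein response; so did leaving out lncMycN siRNA-1 for the first and the last, and lncMycN siRNA-2 for G2/M. The median of ribosome biogenesis was 0.27 without N-Myc siRNA-2. The unfolded protein response call was also lost with the stricter filter and with the mean of a gene's probe sets. The remaining 11 lists were not called, with medians and adjusted p of -0.08 and 0.303 for G1/S, 0.01 and 0.608 for ribosomal proteins, 0.09 and 0.528 for p53 targets, and -0.25 and 0.303 for the adrenergic list. They were -0.10 and 0.0678 for mesenchymal and Schwann cell markers, -0.10 and 0.146 for interferon response, -0.08 and 0.368 for cholesterol synthesis, and 0.04 and 0.303 for glycolysis and hypoxia. They were -0.01 and 0.718 for apoptosis regulators, -0.02 and 0.718 for paraspeckle proteins, and -0.13 and 0.303 for the 2p24 neighbours.

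For single genes in this comparison, limma again called 0 of 12890, and 949 had an unadjusted p under 0.05, with 493 higher and 456 lower. If no gene differed, 644.5 would be expected, but genes are not independent, so the excess was not tested. The smallest adjusted p was 0.656. Differences of the genes with the largest moderated t, none past the threshold, ran from 1.48-fold to 4.21-fold. Higher with lncMycN siRNAs were VWDE at 1.67 (SE 0.12), TMEM50B at 1.58 (SE 0.17), TOX at 1.56 (SE 0.15), SGPP2 at 1.46 (SE 0.08), the salt-inducible kinase gene SIK1 at 1.33, the kinase gene STK26 at 1.32, MRPL38 at 1.29, RUBCNL at 1.27, SLCO4A1 at 1.11, N4BP2L1 at 0.93, SRGAP1 at 0.66 and ANKRD36 at 0.56. Lower were RPH3A, which encodes the synaptic vesicle protein rabphilin, at -2.07 (SE 0.15), APOBEC3B at -1.66 (SE 0.08), the mannosidase gene MAN1A1 at -1.39 (SE 0.14), LINC00467 at -1.37, the ubiquitin-like modifier gene UFM1 at -1.36, the corepressor subunit gene TBL1XR1 at -1.25 (SE 0.12), TMEM255A at -1.20, RFPL1S at -1.10, NTM at -0.94, CRISPLD2 at -0.93, SUSD2 at -0.85 and the chromatin remodelling subunit SMARCD3 at -0.81. Other probe sets of SIK1, SUSD2 and UFM1 had the opposite sign.

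**Figure D3:**
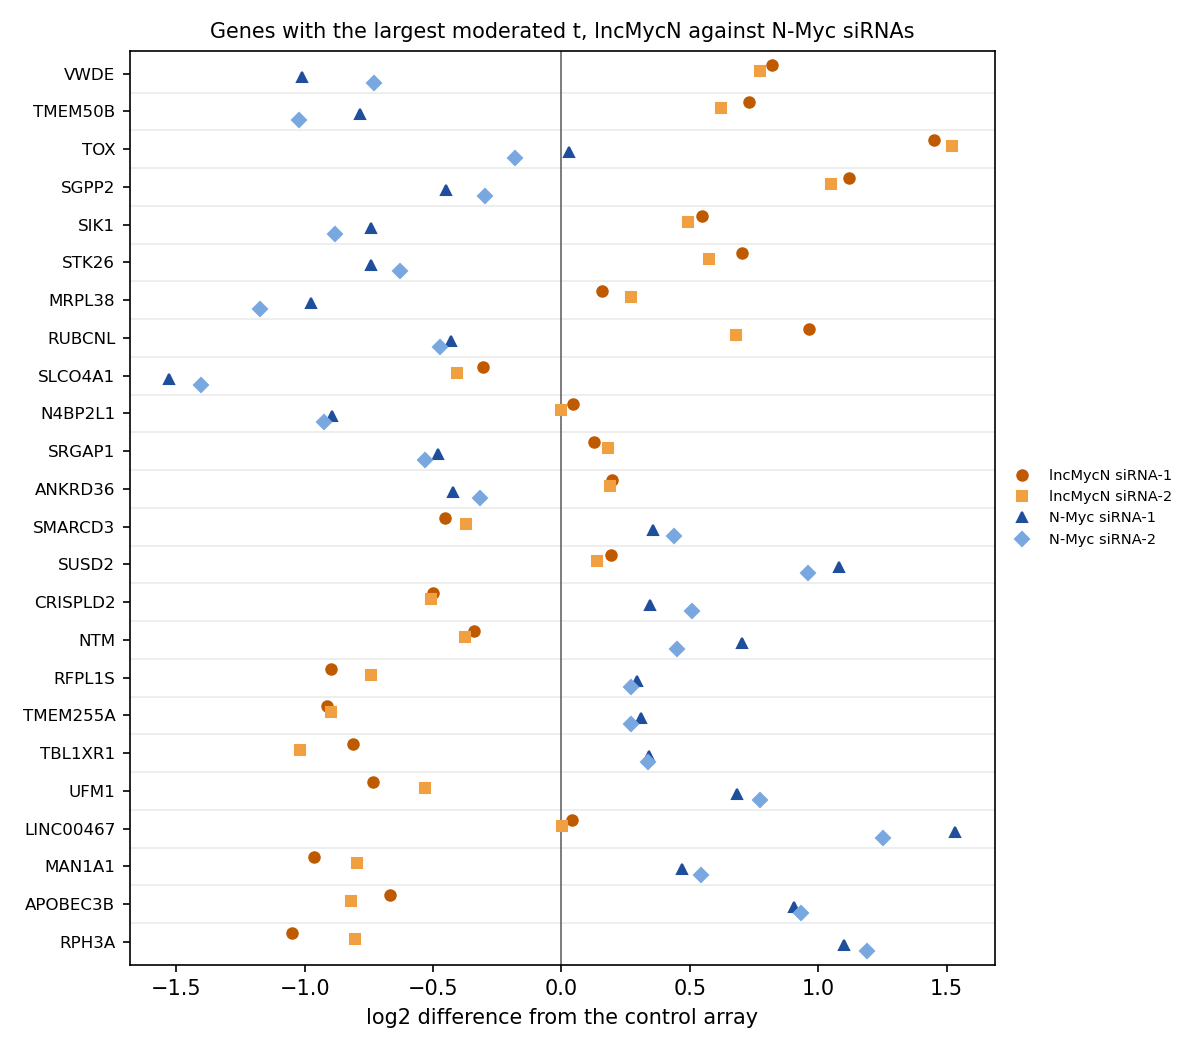
Log2 difference from the control array (horizontal axis) for the 24 genes of largest moderated t between the targets (1 gene per row), with 1 point per siRNA array. RPH3A lies at -1.05 and -0.80 on the lncMycN arrays and at 1.10 and 1.19 on the N-Myc arrays.

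The responses to the targets were then compared across genes. The mean fold changes of the targets correlated with r = 0.313 (Spearman 0.316) over 12890 genes, and their covariance was 0.0298. Because both use the same control array, unchanged arrays with the moderated residual spread gave r = 0.667 and a covariance of 0.0637 in simulation. With 1 control array no split of the control was possible. The N-Myc siRNAs resembled each other more (r = 0.483) than the lncMycN siRNAs did (r = 0.205), and arrays of different targets gave r between 0.186 and 0.239. All these pairs share the control array, and 2 unchanged arrays against 1 control gave r = 0.50 in simulation, above every pair. That simulation uses the same spread, which may be too wide for these arrays, so these r are not placed against chance. Over the covariance across targets, the N-Myc pair had an excess of 0.0392 (95% bootstrap interval over genes 0.0358 to 0.0430) and the lncMycN pair -0.000731 (-0.00410 to 0.00278). Only CCNG2, which encodes cyclin G2, the desmosomal gene DSC2, MIGA1 and THAP9-AS1 were at least 2-fold from the control with all 4 siRNAs, each higher; these 4 were named after their values were seen. Independent lists of these sizes would share 0.0171 higher genes, but both lists use the same control array and so are not independent. The simulation with a shared control gave 25.4 genes at this threshold, at the moderated residual spread, which may be too wide. The overlap is therefore not placed against chance. None of the lower genes was shared, where independent lists would share 0.0621, a value with the same limit.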

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

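The tests of exchanged arrays, of array noise, of the lone control array and the noise-corrected slope were chosen after the results they bear on had been seen.

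In 5 gene lists the targets differed from each other by a test of the difference itself, camera at the preset correlation: median differences, lncMycN minus N-Myc, of 0.43 for ribosome biogenesis, 0.18 for nucleotide, polyamine and one-carbon metabolism, -0.14 for G2/M, -0.32 for neuronal differentiation and 0.19 for the unfolded protein and integrated stress response. None of the 5 was called with an estimated correlation (adjusted p between 0.508 and 0.735). No group has the 4 arrays that a search for outlying arrays needs.

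MYCN stayed close to the control with both N-Myc siRNAs on its brightest probe set, while of the others past the filter 211377_x_at was lower on both arrays (-0.51, SE 0.08) and 209756_s_at (-0.73, SE 0.73) and 234376_at (0.21, SE 0.14) were less certain. An exchange of the arrays of the targets would not account for this, because the lncMycN arrays were as close to the control on the brightest probe set (-0.16). Such an exchange is also argued against by ribosome biogenesis, known as MYCN induced, which was lower on each N-Myc array than on each lncMycN array. The smallest of the 4 differences was 0.25, though the camera call of this list was lost with an estimated correlation (adjusted p = 0.576). Compression of very bright signals may account for the small change: over genes with several probe sets, the slope of the brighter on the dimmer one was 0.108 for 54 very bright probe sets and 0.612 for 1547 mid-range ones, a difference of -0.504 (95% interval -0.566 to -0.427). Because noise in the dimmer probe set also lowers that slope, it was removed with a second dimmer probe set, which left 0.258 (0.0486 to 0.631) in 6 genes against 0.898 (0.827 to 0.973). The second version rests on few genes and removes only noise that the dimmer probe sets do not share. A signal common to both dimmer probe sets but absent from the brighter one would still lower the slope. A weak or transient knockdown of the RNA stays open, as does an effect of the siRNAs on translation.

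The lncMycN siRNAs resembled each other no more than they resembled the N-Myc siRNAs. Noise of dim probe sets is argued against, because with the filter at the upper quartile the excess of r was still 0.00784. The variance between siRNAs of a target, before moderation, was 3.16 times (95% interval 2.92 to 3.46) the observed covariance across targets. Array noise of the same size on all 5 arrays would make these equal if the targets had no effects. Opposite effects of the targets would lower that covariance, so the ratio cannot decide on equal array noise. Different off-target effects of the lncMycN siRNAs may be behind their low resemblance, as may unequal knockdown or a noisier lncMycN array. None of these was tested. An effect of lncMycN shared by its siRNAs stays open at the level of gene lists.

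The G1/S and G2/M lists were lower with both lncMycN siRNAs, while ribosome biogenesis was not; both calls were lost with an estimated correlation (adjusted p = 0.631 and 0.483). All 4 fold changes rest on the lone control array, and G1/S was lower with the N-Myc siRNAs too, so the differences between targets were set against 10000 random lists of the same size and signal, which take no account of correlation between members. For G1/S the lncMycN siRNAs disagreed: the differences of the first from the N-Myc arrays lay at percentiles 41.26 and 63.75, those of the second at 0.92 and 1.71. For G2/M they lay at 4.46 and 4.41 for the first and at 0.15 and 0.54 for the second. A high control value would lower the N-Myc arrays as well. Against the control these lay at percentiles 0.19 and 0.12 for G1/S but at 18.87 and 35.45 for G2/M. For G2/M a high control value alone would leave a gap between targets unaccounted for. That gap is itself uncertain, because its camera call was lost without lncMycN siRNA-2 or without N-Myc siRNA-2. Neither list met either bound of the test, but the bounds were written after the result. The bound for a high control was also changed once after it, and G1/S had met its first form. With 1 control array, a high control value and a decline with the lncMycN siRNAs cannot be told apart for G1/S. For G2/M a contribution of the control stays open, and more control arrays would be needed.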

How the results depend on the processing

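All alternatives were planned before the data were examined. The count of 0 called genes held under every alternative that recounts them, each run in all 3 comparisons except the replicate block, which was run between targets only. With the siRNA number as a replicate block, the comparison of the targets gave 0 called genes, 844 at an unadjusted p under 0.05 and a smallest adjusted p of 0.744; deviations of same-numbered arrays correlated at 0.0121, so the numbers do not pair the arrays, and lists were not run with the block. Every list call was lost with an estimated correlation and with fry, leaving 0 lists in each comparison. The medians were as in the main fit: for N-Myc -0.43, -0.29, -0.21 and 0.15, for lncMycN -0.33, -0.23 and 0.24, and between targets 0.43, 0.18, -0.14, -0.32 and 0.19. These losses do not measure correlation between members alone. The estimate was 0.232 for ribosome biogenesis but -0.00138 for G2/M, under the preset 0.01. For G2/M with lncMycN siRNAs the unadjusted camera p still went from 7.49e-07 to 0.0302. Without the filter the neuronal (0.15) and p53 (0.24) calls were lost; the unfolded protein call was lost at the upper quartile (0.19) and with mean probe sets (0.16). With quantile normalization, median centring and the offset of 32 the 12 calls held. With lncMycN siRNAs 6 lists were called after quantile normalization and 6 at the upper quartile. With an array left out, the number of called lists ran from 3 to 5 for N-Myc, 3 to 5 for lncMycN and 3 to 7 between targets. Medians of the calls lost in this way ran from 0.15 to 0.27 for neuronal differentiation with N-Myc, from 0.053 to 0.41 for p53 targets, and between targets from 0.11 to 0.31 for nucleotide metabolism, -0.19 to -0.086 for G2/M and 0.062 to 0.37 for unfolded protein response. Calls that held ran from -0.48 to -0.30, -0.29 to -0.19 and -0.21 to -0.19 with N-Myc (ribosome biogenesis, nucleotide metabolism, G1/S), from -0.35 to -0.29 and -0.25 to -0.16 with lncMycN (G1/S, G2/M), and between targets from 0.27 to 0.55 (ribosome biogenesis) and -0.38 to -0.24 (neuronal). The neuronal median with N-Myc was 0.088 at the upper quartile. The 36 uncalled results gained a call in 29 of 429 recomputations, 7 of them cholesterol synthesis with lncMycN siRNAs, and their medians changed sign in 28. The 2-fold counts were 28 (N-Myc) and 19 (lncMycN) with log2 of the value plus 32, which shrinks dim differences, and 27 for N-Myc at the upper quartile, which tests fewer genes. They were 445 and 233 at 1.5-fold, 1 and 3 at 3-fold, and with an array left out 62 to 404 (293 without N-Myc siRNA-2) and 30 to 338 (330 without lncMycN siRNA-1), since a single siRNA then decides. The correlation between targets was 0.387 without a filter, 0.257 at the upper quartile, 0.346 with mean probe sets and 0.218 to 0.274 with an array left out. MYCN turned positive on 234253_at (0.41 with N-Myc, 0.28 with lncMycN), 234298_at (0.071, lncMycN), 234376_at (0.21, N-Myc), 234815_at (0.053, N-Myc) and 242026_at (0.12, N-Myc), of which 234376_at alone passes the filter; with an array left out it ran from -0.21 to -0.09 (N-Myc) and -0.17 to -0.15 (lncMycN). Between targets MYCN was 0.014 with mean probe sets and -0.073 to 0.048 with an array left out (0.048 without N-Myc siRNA-2), DDX1 was 0.10 with lncMycN without its first siRNA, and NBAS -0.0081 with N-Myc without its second. Of 3213 recomputed values of the genes under the naming rule, 3183 kept their sign and 0 passed the threshold. Where no reason is given, the cause was not tested. Dim probe sets limit the named genes, many of which lie near the filter's signal of 49.2.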

Other observations

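Canonical histone genes of the H1, H2A, H2B, H3 and H4 families, noticed after the values were seen, lay above the control on most arrays. Of 24 measured, 16 were higher with lncMycN siRNA-1, 21 with lncMycN siRNA-2, 24 with N-Myc siRNA-1 and 22 with N-Myc siRNA-2, and their medians were 0.18, 0.65, 0.38 and 1.07. The linker histone gene H1-2 lay at 0.15 and 1.41 with the lncMycN siRNAs and at 1.60 and 1.57 with the N-Myc siRNAs. H2BC12 lay at 0.45, 1.27, 0.87 and 1.19 in the same order, and H2AC6 at -0.60, 2.11, 1.14 and 1.37. Near-identical family members share probes, so single members are uncertain. These genes were picked because they lay high, so a test of their height on the same arrays tells nothing, and no explanation is offered.

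At least 1.5-fold differences from the control with all 4 siRNAs were seen for 57 genes, 30 higher and 27 lower. Arrays simulated without any effect gave 134 on average, at a spread that may be too wide for these arrays (simulated covariance 0.0637 against 0.0298 observed). The count is therefore not placed against chance. Among the lower ones were (lncMycN arrays first, then N-Myc arrays) KCNQ5 (-0.84, -0.80, -1.34 and -1.97) and LEF1 (-1.86, -0.60, -1.12 and -1.30), and among the higher ones MBNL2 (0.97, 0.93, 0.88 and 1.16) and COG6 (0.81, 0.88, 1.04 and 0.93), named after their values were seen.

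MYCNUT, an RNA gene next to MYCN, was below the signal filter on its probe set, at 41.1 on the control array, 42.0 on both lncMycN arrays and 45.9 and 42.0 on the N-Myc arrays. The labels do not say whether it is lncMycN, so these values check no knockdown.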
